A study of Mus musculus with 4 samples.

How the data were processed

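Epidermis was separated from dorsal skin of mice at postnatal day 0, dissociated, and cross-linked in 1% formaldehyde for 10 min, and chromatin from pelleted cells was sheared to about 300 bp and precipitated with the p63 antibody EPR570, per the labels' protocols. The series held 4 samples, a ChIP and an input for WT and for alphaKO, with 1 of each. The 2 ChIP samples were analysed from 1 peak list each; the input samples were not used here. How many animals entered each sample, their sex and their strain are not given in the sources used here.

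The authors' peak lists are tables in the format of MACS2. Per the submitters' processing notes, Bowtie2 and MACS2 2.1.1.20160309 were used with the mm10 build; the version of Bowtie2, the options of the peak caller, the handling of duplicate reads and the control library of each call are not given in the sources used here. Per the file headers, the authors deposited for each peak a start, end, summit and length, the pileup at the summit (a coverage signal), −log10 of the p-value, a fold enrichment (a ratio of the summit's pileup to the caller's local background), and −log10 of the q-value. The smallest −log10 q was 1.31 in WT and 1.36 in alphaKO. Each list came from a single library, so no pooled calls were involved. Peaks were numbered up to 10642 in WT and 14624 in alphaKO, with 26 and 31 numbers not used in the lists.

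Peak lists carry no read totals, so depth is known only in relative terms. The local background of a peak was recovered as the pileup plus 1, divided by the fold, minus 1, and its minimum divided by the smallest peak width, taken as the fragment length, served as a depth index. This holds only if both calls used the same genome size and unscaled ChIP pileups. A background above 50 marked repeat-like places and applied to 27 WT peaks (0.254%) and 22 alphaKO peaks (0.151%), which were kept in the main results.

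Overlap meant at least 1 shared bp. Shares carry 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules and peaks are not replicates. Chance overlap came from 100 random placements of the peaks on their own chromosomes, between the lowest and highest position of any peak or gene there. Quintiles were ranked within each list by fold. No test between genotypes was made, because each genotype had 1 library.

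Gene names and positions came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes. This table has no strand, exons or sequence. Plans to use transcription start sites were therefore replaced: proximity was measured to either end of a gene (within 1 kb), a gene counted as marked when a summit lay in its body or within 10 kb on either side, and peaks were named by the gene that contains the summit or is nearest to it. Whether a peak was exonic or intronic was not analysed here, nor were p63 motifs. Gene lists were fixed before the data were examined and held 246 entries in 17 lists, of which 3 had no match of their own, leaving 232 distinct genes, 131 with a peak in each list. Each list's count of marked genes was placed among 10000 random lists of the same size, matched on gene length in 20 bins, and the percentile describes these libraries only.

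The rule for named genes, also fixed before the data were examined, took Trp63 and the list linked to AEC syndrome, up to 4 genes of each other list marked in both libraries with the highest WT fold, up to 3 marked in a single library with the highest fold there, and the genes of the top 10 peaks by fold in each list and among peaks without a partner. A fold printed for a gene of a list belongs to its strongest peak in that library, which need not be the same site in both. Some genes that the rule takes are not reported here.

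Alternatives were stricter q and fold thresholds, other definitions of overlap, equal list lengths, other ranking, other distances to genes, and exclusion of Y peaks; excluding peaks with a background above 50 was added after the data were seen. The code was tested on simulated data: with 60.07% of 10616 simulated WT peaks planted in a simulated alphaKO list, 60.4% were recovered as overlapping and 0 planted peaks were missed, and 200 of 200 planted genes and 500 of 500 planted peaks at gene ends were found. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.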

Results

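Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate p63, the transcription factor that maintains stratified epithelia, in mouse epidermis taken from dorsal skin at postnatal day 0. A wild-type sample (WT) and a sample labelled p63 alphaKO (alphaKO) were compared, with 1 ChIP library per genotype and an input library for each, which was not used here. The title of the series names p63 isoforms and AEC syndrome, a skin disorder caused by dominant mutations in the p63 gene, and the comparison asks where p63 lay on chromatin in the alphaKO epidermis relative to WT. With 1 library per genotype there was no replicate spread, so no difference between genotypes was tested, and 95% Wilson intervals cover counting error only. Fold enrichment values are the authors' own, belong to each peak within its own list, and are set side by side below as a description, not as a measure of change between genotypes. A pair of folds printed for a gene of a list belongs to its strongest peak in each library. For some genes, among them Lama3, Nectin1 and Gli2, these peaks were at different sites.

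Both libraries held many p63 peaks at genes of the epidermis. The WT list had 10616 peaks covering 4.74 Mb, with a median width of 385 bp, a median fold enrichment of 8.44 (quartiles 5.21 and 14.1) and a median −log10 q of 42.0. The alphaKO list had 14593 peaks covering 6.38 Mb, with a median width of 401 bp, a median fold of 15.5 (quartiles 9.85 and 27.2) and a median −log10 q of 87.7. A relative depth index recovered from the peak caller's lowest background was 1.11 times as high in WT as in alphaKO, if both calls used the same settings. The number of reads per library was not analysed here.

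Trp63, the gene that encodes p63 (chromosome 16, 25683763 to 25892088, mm10), carried 5 WT and 4 alphaKO peaks within its body. The strongest WT peak of the locus, at 25843245 to 25844251, had a fold of 109.6 and ranked 4 in the whole WT list, and the alphaKO peak there, at 25843488 to 25844200, had a fold of 100.3. Peaks of both lists also met at 25835936 (WT summit, fold 38.5, with 66.3 in alphaKO), at 25765965 (19.0 and 26.9) and at 25725655 (10.6 and 25.4). The remaining WT peak, at 25780042 to 25780347 with a fold of 5.96, had no alphaKO partner. ChIP peaks at this gene do not measure its transcripts, so they check neither the genotype label nor which isoforms were present.

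**Figure D1:**
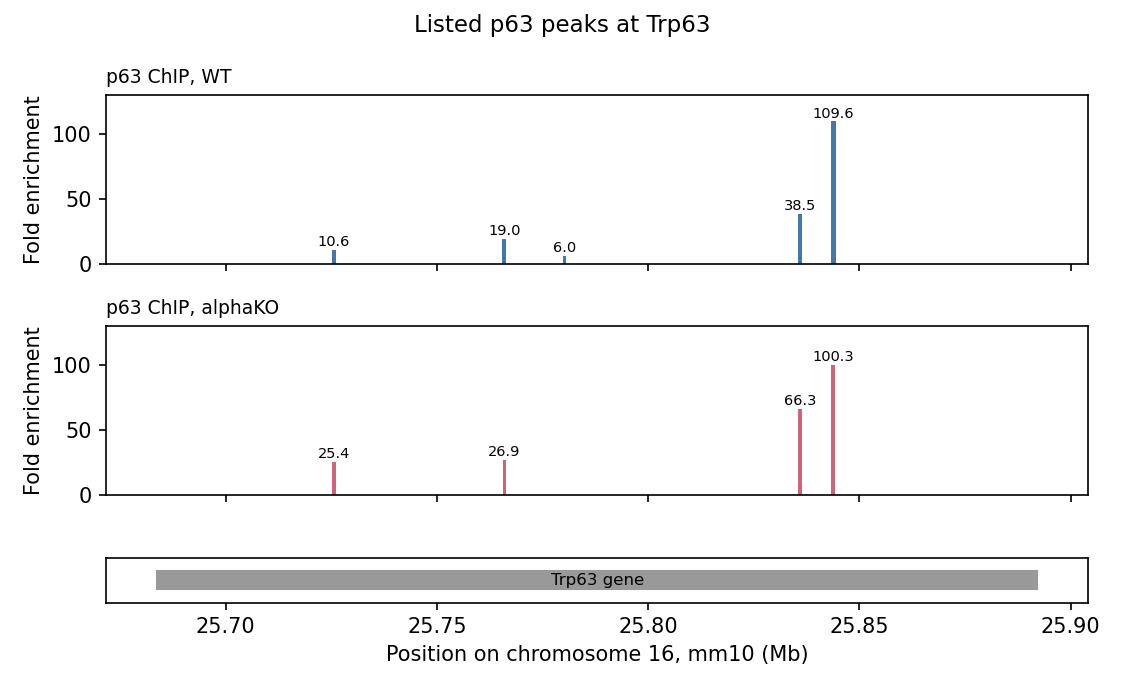
Fold enrichment (y axis) of each p63 peak at the Trp63 gene against position on chromosome 16 (x axis, mm10) in the WT and alphaKO lists, 1 library each. Of the 5 WT peaks, 4 meet an alphaKO peak, and the strongest WT peak has a fold of 109.6.

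In the full lists, a majority of the WT sites were also listed in alphaKO, whereas a majority of the alphaKO sites had no WT partner. Of the 10616 WT peaks, 7066 (66.6%, 65.7 to 67.5) shared at least 1 bp with an alphaKO peak, and of the 14593 alphaKO peaks 7070 (48.4%, 47.6 to 49.3) shared at least 1 bp with a WT peak. Placing the other list at random on its chromosomes 100 times gave mean overlaps of 0.516% and 0.373%. At the 7054 sites where each list's best partner was the other's, summits lay a median of 8 bp apart, and 95.1% lay within 100 bp. Across these sites, which are not replicates, the ranks of the fold values in the lists had a Spearman rho of 0.72. With the longer list reduced to as many peaks as the shorter, both directions gave an overlap of 54.4%. Peaks of the lists met almost 1 to 1, so equal lengths give nearly equal shares in any case. This setting therefore does not test the contrast between directions, which follows from the unequal list lengths.

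The overlap was nearly complete for the strongest WT peaks and incomplete for the strongest alphaKO peaks. In quintiles (5 groups of equal size) of the WT list ranked by fold, from weakest to strongest, 19.7%, 44.5%, 75.2%, 94.1% and 99.3% of peaks met an alphaKO peak. The same quintiles of the alphaKO list gave 38.9%, 30.5%, 40.3%, 56.3% and 76.1%. In the strongest quintile, 15 WT peaks (0.707%, 0.429 to 1.16) and 696 alphaKO peaks (23.9%, 22.3 to 25.4) were without a partner. The median fold was 11.5 for WT peaks with a partner and 4.79 for those without, and 21.0 and 12.8 in the alphaKO list.

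**Figure D2:**
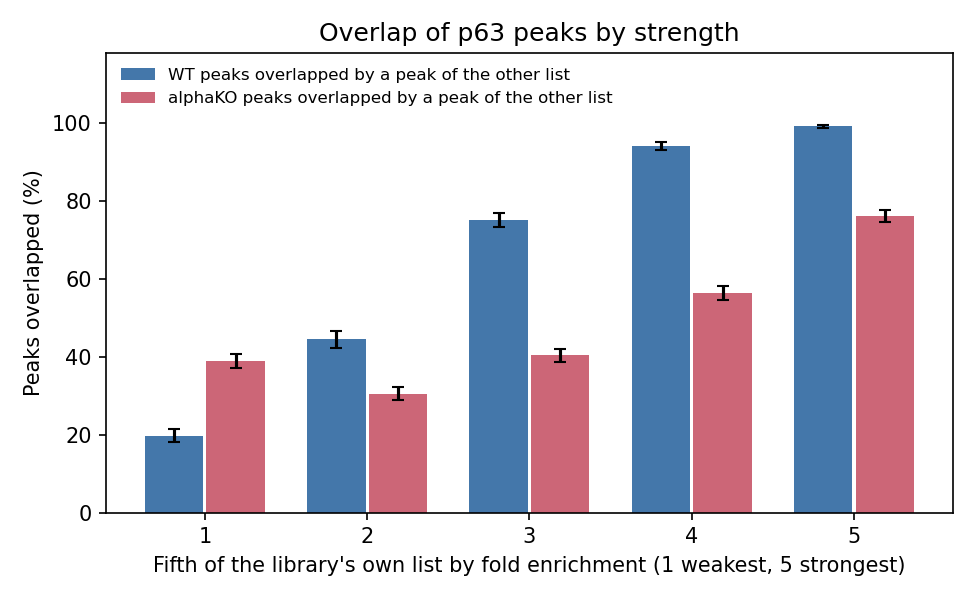
Share of peaks overlapped by the other list (y axis, percent) in quintiles of each list ranked by the authors' fold enrichment (x axis, weakest to strongest), with 95% Wilson intervals, 1 library per genotype. The strongest quintile reaches 99.3% in WT and 76.1% in alphaKO.

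The 10 peaks with the highest fold in each list had 1 gene in common, Zmiz1. The WT list was led by peaks in Dusp7, a phosphatase acting on MAP kinases (fold 167, chromosome 9, 106370608 to 106371621), 7.15 kb outside Cdh3, which encodes P-cadherin (127), 134 kb from Zmiz1 (125), in Trp63, in Hras (109), and 1.10 kb from Gltp, a glycolipid transfer protein (95.6). Peaks 1.03 kb from Cebpa (92.8), 26.9 kb from Egfl7 (91.4), and in Ppm1f (90.8) and Ajuba (90.6) completed its top 10. Each of these 10 peaks had an alphaKO partner. The alphaKO list was led by peaks in Cops7a (382, chromosome 6, 124989583 to 124990666), beside Ndufa7 (341), in Nid2, which encodes a basement membrane protein (323), in Lhfpl3 (314), 134 kb from Zmiz1 (285), and in Tmem40 (267), Antxr1 (259) and Tubgcp3 (250). Hhip, an antagonist of hedgehog signalling, had a peak 46.0 kb away (251), and of the 10 only the peak 259 kb from Dipk2a (237) had no WT partner.

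Sites listed in alphaKO alone reached folds far up their list. After Dipk2a, the strongest lay in Mpped1 (205, chromosome 15, 83852190 to 83852746) and Mctp1 (194, chromosome 13, 76445005 to 76445798). Next came peaks 21.1 kb from Gm8439 (167), 19.7 kb from Cpeb2 (154), 74.2 kb from Rb1cc1 (152) and 19.3 kb from Fam3b (143). Rb1cc1 itself was marked in WT only, by a peak with a fold of 3.22. Sites in Rsph6a (135) and 5.85 kb from Bpifb1 (133.5) followed. Of the 7523 peaks listed in alphaKO alone, 21.5% exceeded the median fold of alphaKO peaks with a partner. The strongest sites listed in WT alone lay in Chdh (21.9, chromosome 14, 30008807 to 30009306), Pak3 (21.3), Agap1 (21.3) and Mpzl2 (21.1), 21.3 kb from Tlr2 (19.8), in Rdh12 (19.6), and 0.216 kb from Epgn, which encodes the growth factor epigen (19.6). Sites 67.4 kb from Atp10b (18.9) and in Il11 (18.1) followed. Of the 3550 peaks listed in WT alone, 2.08% exceeded the median fold of WT peaks with a partner.

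Peaks in a single list differed in where they lay relative to genes. A summit lay within 1 kb of either end of a protein-coding gene for 11.4% (10.7 to 12.1) of WT peaks with a partner and for 30.2% (28.7 to 31.8) of those without. In the alphaKO list the shares were 11.3% (10.6 to 12.1) with a partner and 5.46% (4.97 to 5.9999) without, beside about 3.10% in random placements. Peaks without a partner were also weaker. With fold matched, a comparison chosen after the results were seen, their numbers near a gene end were 1.35 (WT) and 0.419 (alphaKO) times those expected from peaks with a partner. The median distance to the nearest gene end was 17.8 kb for shared peaks of either list, 7.86 kb for WT peaks without a partner and 26.9 kb for alphaKO peaks without a partner. In both lists, 50.9% (WT) and 50.1% (alphaKO) of summits fell inside a gene body, above the 41.6% and 41.0% that were the highest of 100 random placements. The annotation used gives no strand, so starts and ends of genes were not separated.

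Of 21887 protein-coding genes, 4453 (20.3%) had a summit in the gene or within 10 kb of it in both lists, 1316 (6.01%) in WT only and 2253 (10.3%) in alphaKO only. The order of the single-list counts depended on the setting: with equal list lengths they were 1894 and 1574, counting only peaks within 5 kb of gene ends they were 1354 and 1187, with flanks of 50 kb they were 1343 and 3085, and at −log10 q of at least 10 they were 833 and 2397. A gene absent from a list can hold a site under that list's threshold.

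Genes of the basal layer and its anchoring structures carried p63 peaks in both libraries. Of 20 such genes, 18 had a WT peak and 20 an alphaKO peak, where length-matched random lists of genes had medians of 7 and 9, and no random list of 10000 reached either count. Among the strongest in WT were Cdh3 (fold 127 in WT, 173 in alphaKO), Lama3, which encodes a chain of laminin 332 (50.3 and 81.0), and Dst, a hemidesmosomal plakin (38.3 and 47.2). Itgb1 (31.0) and Bcam (26.7) had peaks in alphaKO only. Counting only peaks within 5 kb of gene ends, 11 and 12 of the 20 genes were marked. Of 16 genes of desmosomes and cell adhesion, 14 had a WT peak and 13 an alphaKO peak, against random medians of 5 and 6 (percentiles 100 and 99.985). They were led by Nectin4 (62.2 and 43.1), Dsp, which encodes desmoplakin (57.8 and 78.9), Nectin1 (48.6 and 67.8) and Pkp3 (42.1 and 74.6), while Dsg2 (6.66) and Ocln (5.24) had peaks in WT only and Cldn1 (10.7) in alphaKO only.

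Of 21 suprabasal and cornified envelope genes, 13 had a WT peak and 15 an alphaKO peak, against random medians of 5 and 5 (percentiles 99.995 and 100). Sfn, which encodes 14-3-3 sigma (34.9 and 72.2), Krt10 (30.0 and 53.7), Ppl (28.3 and 41.9) and Casp14 (27.8 and 79.1) were the strongest in WT. Dsc1 (5.90) and Krt1 (2.93, 5.01 kb outside the gene) had a peak in WT only, the Krt1 peak being lost at −log10 q of at least 10, and Dsg1a (17.5), Tgm5 (16.3) and Flg, which encodes filaggrin (14.2), in alphaKO only. Of 15 barrier lipid genes, 6 had a peak in each list, near the random medians of 4 and 5 (percentiles 81.5 and 71.9). They included Cers3 (17.8 and 26.6), Abca12 (11.1 and 35.6) and Ugcg (8.60 and 32.0).

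The list of transcription regulators of the epidermis included 7 genes marked in WT only and 1 marked in alphaKO only. It also holds the Notch receptor gene Notch1 and the Notch ligand genes Jag1 and Jag2. Of its 31 genes, 27 had a WT peak and 21 an alphaKO peak, above every random list (medians 8 and 9). At −log10 q of at least 10 the genes with a peak numbered 25 and 20, and with gene ends within 5 kb 24 and 15. Trp63, Cebpa (92.8 and 73.4), Jag2, a Notch ligand (90.3 and 154), and Ovol1 (50.4 and 30.0) were the strongest in WT among those marked in both. The genes marked in WT only were led by Id1 (9.54), Hopx (7.93) and Grhl1 (7.87), and the weakest of them had a fold of 2.46. Runx1 was marked in alphaKO only (31.0, with 5 peaks). Of 15 chromatin regulators, 9 had a WT peak (random median 5, percentile 97.0) and 5 an alphaKO peak (random median 7, percentile 20.3). At −log10 q of at least 10 these counts were 7 and 5, and with gene ends within 5 kb they were 6 and 2. Satb1, a chromatin organiser (15.3 and 18.5), Chd7 (10.5 and 18.9), Hdac1 (7.73 and 19.9) and Dnmt1 (7.73 and 13.8) had peaks in both, although no Dnmt1 peak of either list had a partner. Kmt2d (6.65) and Dnmt3a (4.32, lost at the stricter q) were among those marked in WT only. The difference between the counts of the 2 lists was not tested.

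Among 12 genes linked to AEC syndrome or to p63 in skin, 11 had a peak in each list and 10 in both, against random medians of 4 and 4. With gene ends within 5 kb, 8 had a WT and 6 an alphaKO peak. Krt5 and Krt14, the keratins of the basal layer, had strongest folds of 17.3 and 26.8 in WT and 46.1 and 52.7 in alphaKO. The fibroblast growth factor receptor genes Fgfr2 (25.9 and 57.1) and Fgfr3 (8.40 and 24.96) had peaks in both lists, although the strongest Fgfr3 peak of alphaKO had no WT partner. Dsc3, a desmosomal cadherin gene, had folds of 24.9 in WT and 11.2 in alphaKO at a shared site (chromosome 18, 20001912 to 20002477). This site lay within 1 kb of the gene boundary with the higher coordinate, which without strand may be its start or its end. Bcl11b had 4 WT and 6 alphaKO peaks, the strongest at 17.7 and 51.8. Dsg1a was marked in alphaKO only, and Krt1 in WT only by its weak peak, without which 10 genes had a WT peak. Several genes of this list also stand in the lists above.

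Targets of the p53 pathway, whose family includes p63, had a peak for 16 of 20 genes in each list, 15 of them in both, above every random list (medians 5 and 5). Bbc3, which encodes the apoptotic protein PUMA (79.7 and 100.8), Mdm2 (46.5 and 66.1), Phlda3 (38.7 and 56.2) and Pmaip1 (26.9 and 39.0) were the strongest in WT. Plk2 (2.96, lost at −log10 q of at least 10) had a peak in WT only and Sesn2 (22.5) in alphaKO only. Of 20 hair follicle genes, 13 had a WT peak and 15 an alphaKO peak, against random medians of 5 and 6 (percentiles 99.985 and 100). Wnt10a (56.9 and 99.8), Gli2 (32.6 and 46.8), Foxn1 (31.3 and 70.6) and Dlx2 (27.8 and 26.4) led them, and Msx1 (16.3) and Krt79 (10.5) were marked in alphaKO only. With gene ends within 5 kb, 8 and 9 of these genes were marked.

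Genes of other cell types mostly lay within the range of random lists. Of 10 melanocyte markers none had a WT peak and 1, Dct (13.2), an alphaKO peak, against random medians of 3 and 4 (percentiles 1.12 and 3.29). Of 10 immune markers none had a peak in either list (percentiles 3.19 and 2.07). With flanks of 50 kb, 3 and 5 melanocyte markers and 5 and 6 immune markers had a peak, but random lists were not drawn for that setting. Of 10 dermal fibroblast markers, 1 had a WT peak and 4 an alphaKO peak, against random medians of 3 and 3. Vim (21.8 and 26.3) was marked in both, and Lum (92.6), Dcn (11.9) and Twist2 (8.45) in alphaKO only. Of 8 endothelial markers 3 and 4 had a peak (percentiles 48.2 and 53.4), namely Pecam1 (40.8 and 56.2), Vwf (13.4 and 16.5) and Erg (6.71 and 20.8), with Tek (9.26) in alphaKO only. Of 6 Merkel cell markers 1 and 2 had a peak, Piezo2 (8.28 and 19.6) in both and Syp (13.2) in alphaKO only, although the strongest Piezo2 peak of alphaKO had no WT partner. Liver genes (1 and 2 of 12) included Apoa1 (8.54 and 12.3) and, in alphaKO only, Ahsg (22.3). Neuron genes (4 and 2 of 12, percentiles 46.7 and 2.61) included Rbfox3 (16.2 and 52.9) and Syt1 (8.77 and 24.8), with Gria2 (5.76) and Camk2a (4.87) in WT only. With gene ends within 5 kb, no endothelial or Merkel cell marker had a peak in either list, and 1 neuron gene had a peak in each. Dermal fibroblast markers then numbered 0 and 3, and liver genes 0 and 1. Of 5 keratins of simple epithelia, 3 had a peak in both lists (percentiles 96.6 and 95.9), Krt8 (35.7 and 65.4), Krt7 (20.3 and 23.5) and Krt19 (12.04 and 22.7), the Krt19 peak being the peak also assigned to Krt15.

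**Figure D3:**
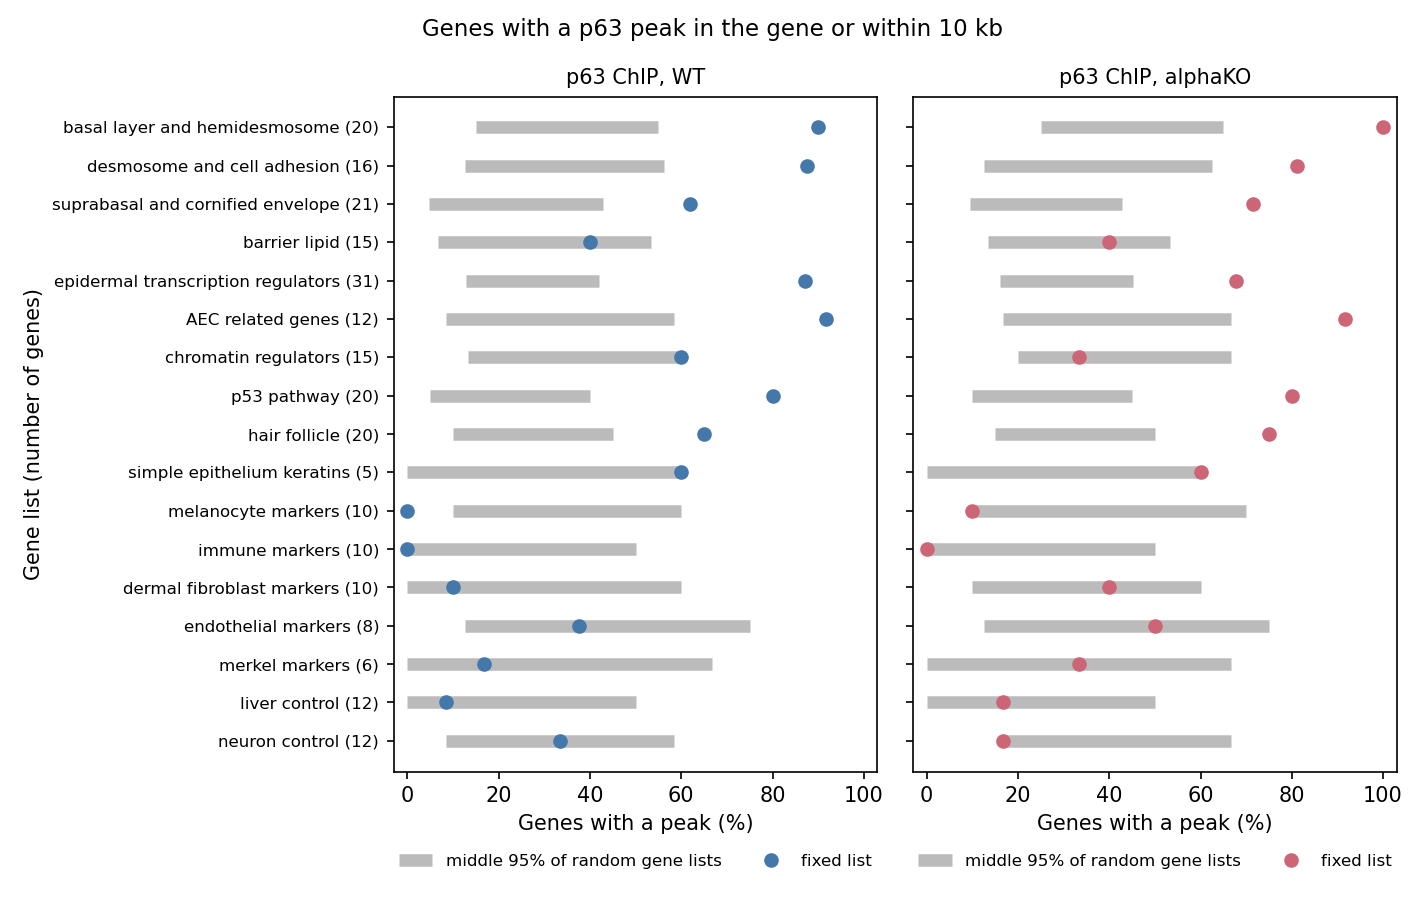
Share of genes with a p63 peak in the gene or within 10 kb (x axis, percent) for each gene list (y axis, number of genes in brackets) in the WT and alphaKO lists, 1 library each, beside the middle 95% of 10000 length-matched random lists (grey bars). Basal layer genes reach 90.0% in WT and 100% in alphaKO, and immune markers are at 0% in both.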

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

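None of the alternatives reversed a direction that was called, since no test between genotypes was made, but 2 statements turned. With equal list lengths 54.4% of WT and 54.4% of alphaKO peaks had a partner, so the alphaKO peaks without a WT partner were no longer a majority. That the 2 shares were equal is built in, since peaks met almost 1 to 1, and does not test the contrast between directions. The order of the counts of genes marked in WT only and in alphaKO only turned from 1316 and 2253 to 1894 and 1574 with equal list lengths, and to 1354 and 1187 with gene ends within 5 kb, while it held at 1343 and 3085 with 50 kb flanks and at 833 and 2397 at −log10 q of at least 10. Of the main results, 47 comparisons with an alternative stayed within the interval or within 1.5 times of the count and 39 moved further; for single gene lists these numbers were 75 and 27. The filter on background above 50 was chosen after the data were seen, and moved no main result beyond those limits. The causes of the shifts below were not tested. The share of WT peaks with an alphaKO partner, 66.6%, became 68.2% at −log10 q of at least 5, 72.3% at 10, 73.8% with that limit on the WT list alone, 78.2% at a fold of at least 5, 63.01% with 50% overlap of both peaks, 63.3% with summits within 100 bp and 67.5% within 500 bp. The share of alphaKO peaks with a WT partner, 48.4%, became 47.5% at −log10 q of at least 10, 45.8% at a fold of at least 5, 45.8% with 50% overlap and 46.0% with summits. Ranking by −log10 p gave 80.1% for the strongest and 34.2% for the weakest alphaKO quintile. With summits, the strongest WT quintile was at 98.4%, the weakest WT quintile at 13.8% and the weakest alphaKO quintile at 31.0%. Shares near gene ends for all, shared and single-list peaks became 32.9%, 27.2% and 44.3% (WT) and 22.3%, 27.2% and 17.7% (alphaKO) within 5 kb. With all annotated genes they were 23.1%, 16.4% and 36.5% (WT) and 12.8%, 16.4% and 9.40% (alphaKO). At −log10 q of at least 10 they were 14.6%, 10.6% and 25.1% (WT), and 7.86% (all) and 10.6% (shared) in alphaKO; single-list WT peaks stayed above, and single-list alphaKO peaks below, shared peaks in each of these settings. Genes marked in both lists numbered 2174 with gene ends within 5 kb and 8964 with 50 kb flanks. The alternatives on p63 motifs were not run, and no library can be left out with 1 per genotype. No paired analysis was possible because each genotype has 1 library. Depth limits the reading of absent peaks, since a site under a list's threshold is missing from it.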

Other observations

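The tests of the strong alphaKO peaks, of the fourth quintile of the WT list, of gene ends at matched strength and of the X chromosome were chosen after the results were seen; the test of the weakest WT quintile was planned before its result was seen. The genes in this paragraph were also chosen after their values were seen. Among genes marked in WT only, Bcl3 had 6 peaks (strongest fold 7.49), Bcor and Id1 had 4 each (9.81 and 9.54), and Nr4a2, Ankrd50 and Esrp1, a splicing regulator of epithelia, had 3 each (16.9, 13.1 and 10.1). Among genes marked in alphaKO only, Pcdh15 had 7 peaks (37.3), Sntb1, Iqch and Ppargc1a, a regulator of mitochondrial genes, had 6 each (63.1, 49.4 and 31.0), and Ntng1 and Runx1 had 5 each (76.8 and 31.0). Peak counts were not adjusted for gene length. Lengths ran from 1.16 kb (Id1) to 124 kb (Bcor) for the WT genes named. For the alphaKO genes named they ran from 181 kb (Iqch) to 1554 kb (Pcdh15). The median length was 34.1 kb for genes marked in alphaKO only, 19.3 kb for those marked in WT only and 34.8 kb for those marked in both. Of alphaKO peaks without a partner, 35.9% (34.8 to 36.9) lay more than 50 kb from any gene end, against 26.8% (25.8 to 27.8) of those with a partner, and 20.5% (19.2 to 21.8) of WT peaks without a partner.

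The first pattern is the 696 strong alphaKO peaks without a WT partner, 23.9% (22.3 to 25.4) of their quintile and 33.8 times (19.2 to 59.3, counting error only) the WT share, values that restate the pattern and decide nothing on their own. Copies of a single fragment would be about as wide as that fragment, but the median width was 1.70 times the smallest in the list (quartiles 1.57 and 1.86). Copies of a few offset fragments could be this wide, so they stay open. A stricter q threshold in WT is argued against by the smallest −log10 q of 1.31 in WT and 1.36 in alphaKO. An even loss of depth or enrichment in WT was considered next. The depth index was 1.11 times as high in WT, but this holds only if both calls used the same settings, which are not given. The pileups of the 696 peaks (median 277) were scaled by the WT to alphaKO ratio at partnered strong peaks. The limit was a pileup of 34.3, percentile 95 of the 38 WT peaks near the threshold, whose median was 26. The median ratio of 0.536 put 100% of the 696 peaks above that limit. The ratio at percentile 5, 0.136, put only 58.9% (55.2 to 62.5) above it, short of the bound of 90% set for excluding an even loss with scatter between sites. Both ratios come from sites that reached the WT list, so they may be too high for peaks that did not. Such a loss, strain sequence, genotype, cell composition and reads of another ChIP may each account for the pattern and stay open.

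The second pattern is that WT peaks without a partner lay near gene ends. Weak peaks as such may lie there. With fold matched in 50 bins, the number of unpartnered WT peaks within 1 kb of a gene end was 1.35 times (1.20 to 1.54, bootstrap over peaks) that expected from partnered WT peaks. Fold in 1 library measures strength with error, and unpartnered peaks may be weaker than partnered peaks of equal fold. The ratio therefore cannot decide whether weakness is the whole cause. In the alphaKO list this ratio was 0.419 (0.371 to 0.472), with 8.52% of unpartnered and 22.4% of partnered peaks near a gene end in the weakest quintile. In the weakest WT quintile the shares were 40.4% and 28.9%, a ratio of 1.40 (1.14 to 1.73) that excludes 1 but not the preset bound of 1.5, and in the fourth quintile, picked after all 5 had been seen, the ratio of 2.74 (1.72 to 4.24) decides nothing. Weakness of the peaks stays open, and so do open chromatin at promoters and a genotype difference, which were not tested.

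The third pattern is the Y chromosome, with 1 WT and 9 alphaKO peaks, and X, with 1.32% (1.12 to 1.55) and 1.84% (1.64 to 2.07) of peaks. A larger share of males in the alphaKO sample may account for the Y peaks and would lower the background on X. Tested first as the ratio of X to autosome background, this gave 0.706 in WT and 0.658 in alphaKO, but 69.5% of alphaKO X peaks sat at the caller's lowest value, so this ratio is an upper limit and does not decide. A second test, devised only after that outcome and with a limit taken from the same alphaKO value, found 55.3% (45.3 to 65.0) of the 94 shared X peaks at low background in alphaKO and 35.1% (26.2 to 45.2) in WT, intervals that barely separate. On autosomes the order was opposite (1.15% in alphaKO and 10.9% in WT). The limit, 0.658 of the autosome median, was the caller's lowest value in alphaKO, while WT values reached down to 0.507. The autosome order may therefore come from the limit and cannot serve as a control for X. The intervals also cover only counting error between single libraries, so the sex of the animals stays an open hypothesis.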
